A study of Mus musculus with 2 samples.

How the data were processed

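The data are UMI counts per gene and cell barcode from 2 libraries, 1 per age, of alveolar macrophages sorted from mouse lung. Libraries were made with a 10x Chromium Single Cell 3′ kit, per the labels' protocols. The authors' deposited matrices hold raw counts, whole numbers without normalization, for 27998 genes, and Cell Ranger 2.0.0 is named in the submitters' processing notes. The genome build, the annotation and the settings of barcode filtering are not given in the sources used here, so no coordinates are printed, and genes carry the identifiers and symbols of the files. The lowest barcode totals were 940 UMIs in the young and 968 in the aged library.

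Barcodes with at least 500 genes and under 10% mitochondrial UMIs were kept, 13590 young and 6089 aged. Cells of both libraries were clustered together without batch correction, since library and age cannot be told apart. Counts were scaled to 10000 per cell and log transformed with scanpy 1.11.5, 2000 variable genes, ranked within each library, were scaled and reduced to 30 principal components with numpy 2.4.6, and a shared neighbour graph of 15 neighbours (scikit-learn 1.9.0) was partitioned with leidenalg 0.10.2 at resolution 0.8. Cell type markers, 22 gene lists, the rule for named genes and all alternatives but those said to be added were fixed before the data were examined, and 813 of their 826 genes were present by symbol. How markers were turned into classes was set after clustering. A cluster counted as alveolar macrophage-like unless the mean log2 CPM of its 20 markers fell more than 1 below that of all cells. It counted as cycling when at least 2 cycling markers were among its 10 leading genes by fold and at least 3 were 2-fold above other cells. Cluster 2 had a marker of another type and none of its own among its 10 leading genes, and against cluster 13 alone so had clusters 1, 3 and 9 (Mmp8, a neutrophil marker). Cluster 2 stayed in the class, and values without it and over all kept cells, which use no class, were computed.

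Doublets were scored with Scrublet in scanpy at an expected rate of 0.08. It marked 0 young and 1 aged cell, under 0.5% of cells, and so did not work here. Doublets were therefore kept, and the 8% of cells with the highest scores in each library were left out as an alternative.

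UMIs were summed per library over each class and given as CPM of the sum. The ratio of aged to young CPM carries an exact conditional (Clopper-Pearson) 95% interval, and shares of cells an exact Clopper-Pearson 95% interval (scipy 1.17.1). UMIs are counted once per molecule, but the intervals leave out differences between animals, sorts and library preparations. Those of the ratios also leave out uneven counts between cells. A count of 0 was read as at most 3 counts. Genes entered the comparison with at least 50 UMIs in both sums together and 20 CPM in the higher library, and list members with at least 20 UMIs, a library at 0 being set to 3 counts. Each list's median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs without replacement, leaving out shallower cells.

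Named genes, by the rule, are the 12 highest and 12 lowest by the interval bound nearest 1, leaving out mitochondrial, ribosomal and mitochondrial ribosomal protein genes, Gm and Rik models and sex-linked genes, plus chosen receptors, regulators, cycle inhibitors and identity genes and up to 4 members per list furthest from 1. Other list members and the cell type markers with values were chosen after their values were seen.

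On Poisson counts simulated from these sums with known changes, intervals held the true ratio for 95.0% of 5730 genes. The intervals assume such counts, so this checks the computation and not the spread between cells or libraries. At least 2-fold differences were called for 100% of genes changed 4-fold, 35.3% of those raised 2-fold and 66.7% of those lowered 2-fold, whose true values sit at the threshold. A list of 30 genes shifted by 0.5 on the log2 scale came out at percentile 100.

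Alternatives covered the cell filter, Leiden resolutions of 0.4 and 1.2, thinning to 1000 UMIs, edgeR 4.0.16 TMM factors, median of ratios factors, the mean of per-cell CPM, count minimums, the cells summed and depth per cell. Clustering each library alone, leaving out cluster 2 and the doublet score alternative were added after the data were seen. Figures were drawn with matplotlib 3.10.9.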

Results

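Alveolar macrophages, the resident phagocytes of the lung's airspaces, were profiled by droplet single cell RNA sequencing in wild type mice of 2 ages. Cells positive for CD11c and Siglec F had been sorted from whole lung by flow cytometry, and 1 library came from mice of 2 months (young) and 1 from mice of 22 months (aged). How many animals went into each library is not stated in the labels. With 1 library per age no difference has a replicate check, no test was possible, and age cannot be separated from anything else that differed between the libraries. All intervals are exact 95% intervals that cover counting error only, and pairs of values joined by "and" give the young library first.

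The young library held 13753 cell barcodes with 43706362 UMIs (unique molecular identifiers, counted transcripts) and the aged library 6313 barcodes with 22402364 UMIs. After filtering, 13590 young and 6089 aged cells remained. The median cell held 3016 UMIs and 1451 genes in the young library and 3418 UMIs and 1612 genes in the aged library. Depth per cell, meaning UMIs per cell here, was thus higher in the aged library. Xist, the transcript of the inactive X chromosome, stood at 1177 CPM (the count scaled to the total of all genes) in the young and 1249 CPM in the aged library. Of 4 Y-linked genes, Ddx3y and Eif2s3y had 0 UMIs in both, Uty had 1 UMI in each and Kdm5d had 1 UMI in the young library alone, where a count of 0 allows up to 0.0693 CPM in the young and 0.139 CPM in the aged sum.

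The first comparison asked what the sort contained. Of 15 clusters, 14 had alveolar macrophage markers near their level over all cells, and 1, cluster 13, fell below it. That cluster held 22 of 13590 young cells (0.162%, 0.102 to 0.245%) and 21 of 6089 aged cells (0.345%, 0.214 to 0.527%). Its leading genes mixed markers of interstitial macrophages and dendritic cells with the fibroblast marker Inmt, so it was left unnamed. In its cells C1qb was at 385 CPM in the young and 540 CPM in the aged library. Inmt was at 0 and 1034 CPM there, and Mfap4, another fibroblast marker, at 0 and 517 CPM. Its shares therefore need not count the same kind of cell. The sort on CD11c and Siglec F sets these shares. In the other 14 clusters, called alveolar macrophage-like below, the mean log2 CPM of the 20 markers, relative to that of all cells, lay between -0.46 and 0.10, and in cluster 13 at -2.24, the measure that defined the class. Detection did not separate them, with all 20 markers detected in cluster 13 and 19 in cluster 14. In cluster 2 Apoe, on the interstitial macrophage list, was among the 10 leading genes against all other cells and no alveolar macrophage marker was. The C1q genes of that list stayed low, with C1qb at 0.0693 CPM in the young and 0.370 CPM in the aged alveolar macrophage-like sum. The ages occupied different clusters: cluster 0 held 4725 of 6068 aged cells, while most young cells lay in clusters 1 to 5, so a value of the class compares largely different clusters, and a cluster mostly of 1 library may be that library and not a cell type. Over all kept cells, which uses no class, 72 genes were at least 2-fold higher and 18 lower in the aged library.

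Identity genes differed by less than 1.5-fold between the libraries, among cells selected in part by such genes. The scavenger receptor gene Marco was at 468 CPM in the young and 398 CPM in the aged library (ratio 0.852, 0.830 to 0.873), Siglecf had a ratio of 0.878 (0.843 to 0.915) and Itgax, which encodes CD11c, one of 0.949 (0.925 to 0.973). Of 24 identity genes none was 1.5-fold apart. Furthest from 1, by the interval bound nearest 1, were Slc7a2 (0.678), Flt1 (1.44), Fabp1 (0.712) and Chil3 (1.33). The list's median log2 ratio of -0.08 lay at percentile 7.13 of random lists matched on expression. Percentiles of this kind describe these libraries. Itgax and Siglecf encode the proteins used for the sort, and both genes, Marco and others of the list are among the markers that defined the class. Selection of this kind favours similar levels in both libraries, so these values cannot tell whether identity was kept with age. In the GM-CSF signalling and regulator list, whose factors maintain alveolar macrophages, 25 of 28 members lay within 1.5-fold. Csf2ra, the receptor's ligand-binding chain, was higher in the aged library at 195 and 244 CPM (ratio 1.25, 1.21 to 1.30), while Csf2rb (1.05), Csf2rb2 (1.09), Pparg (1.08), Runx1 (0.993) and its partner Cbfb (0.909, 0.865 to 0.955) lay closer to 1. Members outside 1.5-fold included Maf, at 1.66 and 3.33 CPM, and the feedback inhibitor Socs3, lower in the aged library at 12.6 and 7.63 CPM. The list's median log2 ratio was 0.00 (percentile 48.5).

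The second comparison concerned proliferation, since the series title names a senescence-like phenotype. Cycling cells made up 11.5% of young alveolar macrophage-like cells (1561 of 13568, 11.0 to 12.1%) and 5.27% of aged ones (320 of 6068, 4.72 to 5.87%), a ratio of 0.458 (0.405 to 0.517). These are cells of clusters 6, 7 and 9, led by replication and mitosis genes. When each library was clustered alone, a choice made after seeing the data, the shares were 6.48% and 3.21%. Mki67, which marks cycling cells, had a summed level of 71.6 CPM in the young and 37.8 CPM in the aged library (ratio 0.528, 0.488 to 0.570). Top2a, which untangles replicated chromosomes, was at 180 and 92.4 CPM (ratio 0.513, 0.488 to 0.539).

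Shares of cells with a UMI gave the same order at equal depth. After every cell was thinned to 2000 UMIs, which left out 3070 young and 928 aged cells, Mki67 was seen in 6.61% (6.14 to 7.10%) of 10498 young and 3.56% (3.07 to 4.10%) of 5140 aged cells, with 7.99% and 4.40% without thinning. Top2a was seen in 7.86% and 4.44% (8.73% and 5.27% without thinning). In cells outside the cycling clusters, with a median of 2924 UMIs in the young and 3374 in the aged library, the thinned Mki67 share was 1.18% and 0.785%, which sets no background, since these cells are those left once clusters high in such genes were set apart. Of 31 cycling markers measured, 26 were seen in fewer aged cells with intervals that did not overlap. Tyms, Pcna, Mcm5 and Tubb5 had overlapping intervals, and the tubulin gene Tuba1b was seen in more aged cells (66.3% and 69.3%).

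**Figure D1:**
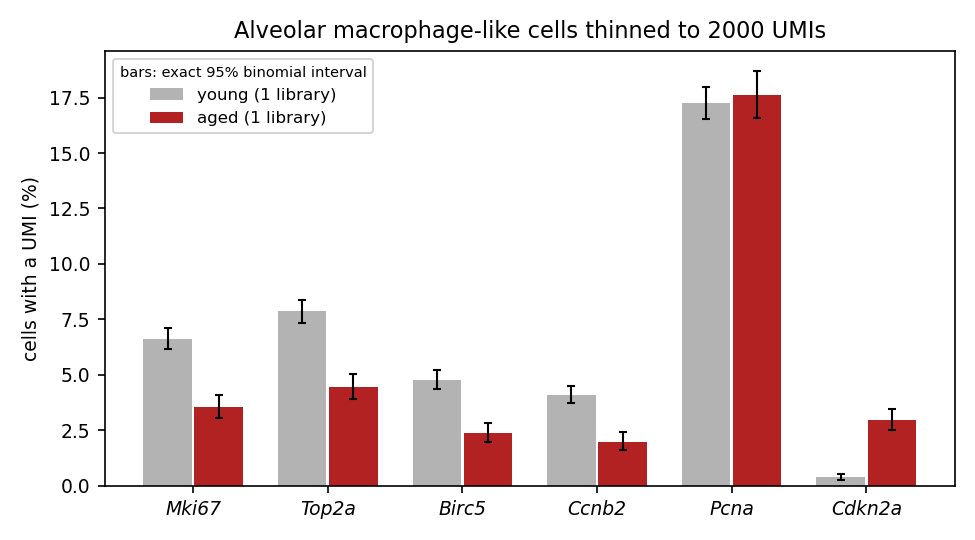
Percent of alveolar macrophage-like cells with at least 1 UMI (vertical axis) of 6 genes (horizontal axis) after thinning to 2000 UMIs, in the young (grey) and aged (red) library, with exact 95% binomial intervals. Mki67 stood at 6.61% in young and 3.56% in aged cells, Pcna at 17.2% and 17.6%, and Cdkn2a at 0.381% and 2.98%.

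Gene lists gave the same direction. Of 52 G2 and M phase genes, 36 were at least 1.5-fold lower in the aged library and 0 higher, with a median log2 ratio of -0.73, below all of 10000 random lists. Nusap1, a spindle protein gene, had a ratio of 0.416 (0.376 to 0.460), Ube2c 0.460 and Ckap2l 0.466. Of 42 S phase genes, 15 were at least 1.5-fold lower and 0 higher (median -0.38, also below all of the random lists), with Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, at 0.426 (0.379 to 0.478), E2f8 at 0.399 and Ccne2 at 0.530. Of 58 DNA repair genes 53 lay within 1.5-fold (median -0.07, percentile 0.160). The 5 lower ones were Neil3 (0.442), Chek1 (0.518), Brca1 (0.532), Pole (0.572) and the replication ligase Lig1 (0.628).

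Among cycling cells alone these lists were not lower. The G2 and M phase median log2 ratio was 0.14 (percentile 99.9) and the S phase median 0.20, and the Mki67 ratio was 1.12 and that of Top2a 1.08. DNA repair stood at 0.11 (percentile 87.1) and MYC targets at -0.06 (percentile 1.21). G2 and M phase genes had 2.76 UMIs per S phase UMI in young (2.72 to 2.81) and 2.62 in aged cycling cells (2.54 to 2.70). In non-cycling cells the G2 and M phase median was -0.29 and the S phase median -0.05, and the DNA repair median was 0.01. Because the cycling clusters are defined by such genes, levels inside them describe the cells assigned there.

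Among cell cycle inhibitors, Cdkn2a, whose products p16 and p19Arf restrain the cell cycle, stood apart. It was at 2.33 CPM (101 UMIs) in the young and 18.7 CPM (404 UMIs) in the aged library, a ratio of 8.01 (6.42 to 10.1). In the young library 68 of its UMIs came from cycling cells and 33 from all others, whereas in the aged library 350 came from non-cycling cells, giving a ratio of 19.4 (13.5 to 28.6) there and 3.44 (2.36 to 4.995) in cycling cells. After thinning, a Cdkn2a UMI was seen in 0.381% (0.272 to 0.519%) of young and 2.98% (2.53 to 3.48%) of aged cells, 0.656% and 4.38% without thinning. In cells outside the class, with median depths of 4970 and 3635 UMIs, it was seen in 0 of 20 and 0 of 16 thinned cells, which allows up to 15% and 18.8%, too few cells to set a background. The neighbouring inhibitor gene Cdkn2b was also higher (1.06 and 4.02 CPM, ratio 3.79, 2.62 to 5.54), as was the cyclin gene Ccnd1 (0.462 and 7.08 CPM, ratio 15.3, 9.58 to 25.8).

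Other inhibitors did not follow Cdkn2a. Cdkn1a, which encodes p21, was at 424 and 420 CPM (ratio 0.988, 0.964 to 1.01), and Cdkn1b (0.771), Cdkn2c (0.507, 0.387 to 0.658) and Cdkn2d (0.769) were lower in the aged library. Most Cdkn2c UMIs came from cycling cells (223 of 288 in the young library), where its ratio was 1.24 (0.927 to 1.65), with 0.253 (0.111 to 0.510) in non-cycling cells. Cdkn2d stood at 1.08 (0.849 to 1.35) in cycling and 1.05 in non-cycling cells. Over the list of 22 inhibitors and senescence markers, 5 members were at least 1.5-fold higher, 3 lower and 14 between, with a median log2 ratio of -0.06 (percentile 5.20). Gdf15, a stress-induced secreted factor, was among those higher (ratio 1.70, 1.62 to 1.78).

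The third comparison took all genes in alveolar macrophage-like cells, from 43268694 young and 21618033 aged UMIs. The libraries were close overall: of 5917 genes abundant enough, 96.0% lay within 1.5-fold, 71 were at least 2-fold higher and 18 at least 2-fold lower in the aged library. Without cluster 2, a choice made after seeing the data, 73 were higher and 50 lower. MHC class II genes, which present antigen to helper T cells, were among the higher genes. H2-Eb1 was at 60.5 CPM in the young and 643 CPM in the aged library (ratio 10.6, 10.2 to 11.1), H2-Aa at 123 and 888 CPM (7.23), H2-Ab1 at 142 and 1012 CPM (7.14, 6.94 to 7.34), and the invariant chain gene Cd74 at 446 and 2752 CPM (6.17, 6.07 to 6.28). Ciita, the transactivator of these genes, had 2.57 and 17.0 CPM (6.62). Of 9 measured class II genes 7 were at least 1.5-fold higher and 0 lower (median log2 ratio 2.63, percentile 100), while H2-DMa (1.07) and H2-DMb2 (0.740) did not follow.

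The class II difference was spread over most aged cells. After thinning, at least 1 UMI of H2-Aa, H2-Ab1, H2-Eb1 or Cd74 was seen in 35.98% (35.1 to 36.9%) of young and 87.4% (86.4 to 88.3%) of aged cells, with medians of 0 and 10 UMIs per cell. For H2-Ab1 alone the shares were 16.4% and 68.9%, or 20.4% and 76.6% without thinning. No cell class that should lack class II was present to give a background. The class I list was higher by less: 4 of 17 members were at least 1.5-fold higher and 0 lower (median 0.43, percentile 100), with H2-Q7 at 2.35, a member of a family of near-identical genes whose reads can be shared. In the interferon response list (median 0.25, percentile 99.8) 6 of 26 genes were higher and 1 lower. Cxcl9, a chemokine, was at 5.55 and 23.2 CPM (ratio 4.18, 3.58 to 4.89), whereas Isg15 (0.916) and Ifit1 (0.877) were not higher.

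**Figure D2:**
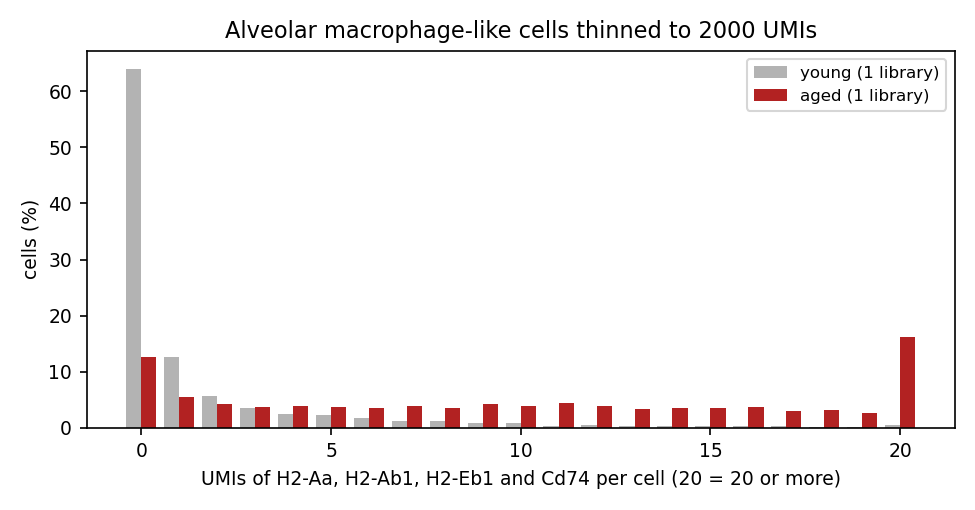
Percent of alveolar macrophage-like cells (vertical axis) by their summed UMIs of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 (horizontal axis, the last bars holding 20 or more) after thinning to 2000 UMIs, in the young (grey) and aged (red) library. Young cells had a median of 0 and aged cells of 10 UMIs.

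The first 4 genes by the naming rule were nearly silent in the young library. Pla2g2d (ENSMUSG00000041202), a secreted phospholipase, had 5 UMIs there and 1287 in the aged library (0.116 and 59.5 CPM, ratio 515, 220 to 1589). The uncharacterised gene AC168977.1 (ENSMUSG00000079808) was at 0.231 and 58.1 CPM. Col4a1 and Col4a2, which encode basement membrane collagen chains and lie head to head in the genome, were at 0.162 and 29.7 CPM and at 0.208 and 39.9 CPM. Hmcn1, another matrix protein gene, had a ratio of 32.0, Trap1a 17.0, the glutamate transporter gene Slc1a3 12.5, Rbms3 10.4 and the calcium-binding protein gene S100a6 7.36 (54.7 and 403 CPM).

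Genes lower in the aged library were fewer. Id3, an inhibitor of helix-loop-helix transcription factors, was at 52.6 CPM in the young and 5.83 CPM in the aged library (ratio 0.111, 0.0918 to 0.133). Apoe, an apolipoprotein that carries exported lipid, was at 61.7 and 13.9 CPM (ratio 0.226, 0.200 to 0.254), and at 0.335 without cluster 2. Cd93 (0.294), Gmfg (0.338), Cbfa2t3 (0.387) and fibronectin, Fn1, at 417 and 193 CPM (0.464, 0.448 to 0.479), followed. Tmsb10, an actin monomer binder, was at 1328 and 684 CPM (0.515). Bcl2a1d (0.419) has near-identical copies and AY036118 (0.313) overlaps ribosomal RNA sequence, so both values are uncertain.

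**Figure D3:**
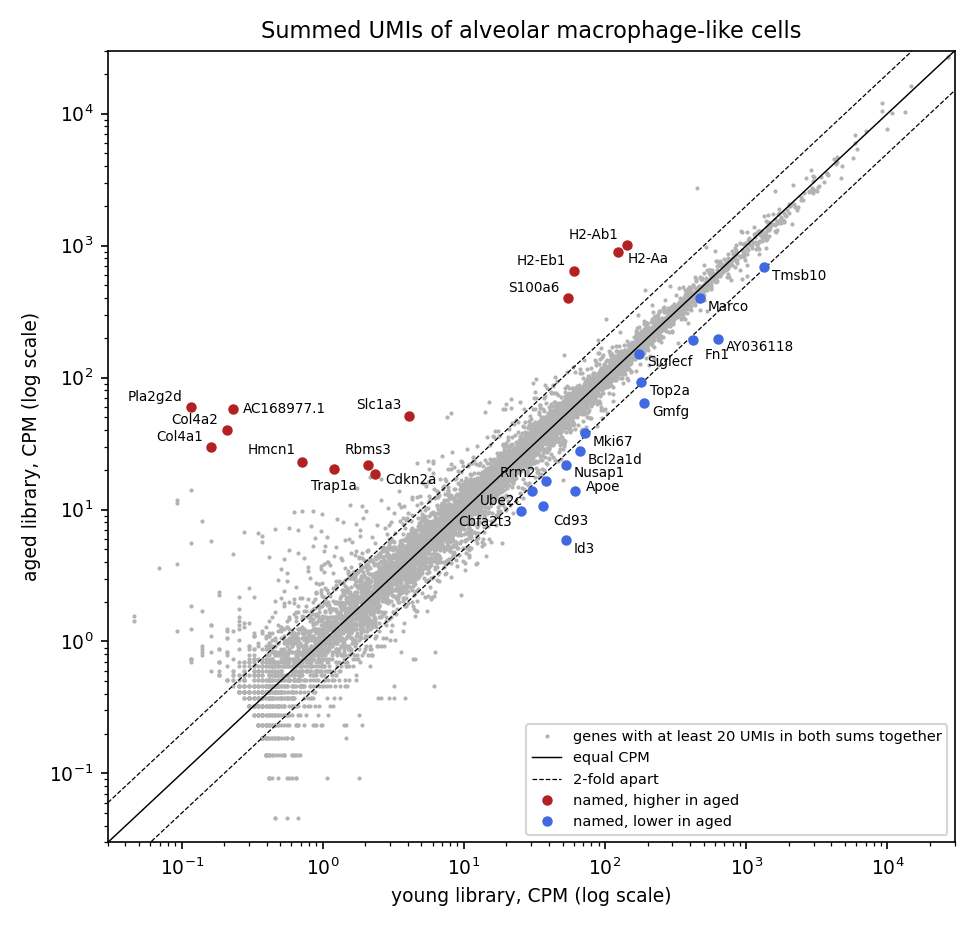
CPM of each gene in the summed alveolar macrophage-like cells of the young (horizontal axis) and aged (vertical axis) library, both on log scales, for genes with at least 20 UMIs in both sums together, with lines at equality and at 2-fold. Some of the genes named in the text are in red where higher and in blue where lower in the aged library, and Pla2g2d (0.116 and 59.5 CPM) and Id3 (52.6 and 5.83 CPM) lie far from the line.

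Secreted inflammatory genes went both ways. Of 33 measured, 7 were at least 1.5-fold higher and 6 lower in the aged library (median log2 ratio 0.01, percentile 45.6). The matrix metalloproteinase genes Mmp12 (3.01, 2.81 to 3.22) and Mmp8 (2.91, 2.75 to 3.07), the growth factor gene Igf1 (2.04) and the chemokine genes Ccl4 (2.09) and Ccl3 (1.62) were higher. The cytokine genes Il6 (17.5 and 9.21 CPM, ratio 0.526, 0.447 to 0.615), Il1b (0.583, 0.549 to 0.618) and Il1a (0.599) and the neutrophil chemoattractant gene Cxcl1 (0.604) were lower. All of these, like the immediate early gene Egr1, were among the 10 leading genes of cluster 4, which held 1846 young and 128 aged cells. How much of the difference comes from that cluster's share of cells was not tested. Immediate early genes, which respond to tissue dissociation, were slightly lower too (median -0.08, percentile 1.62), with Fos at 0.699 and Egr1 at 0.707, and 3 of 31, Socs3 (0.605), Gadd45b (0.654) and Dusp2 (0.523), lower by 1.5-fold or more. In the tissue remodelling list 3 of 16 were higher and 1, Fn1, lower (median 0.22, percentile 99.9), and Spp1 had a ratio of 1.43.

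Cholesterol synthesis genes were modestly higher in the aged library, with a median log2 ratio of 0.29 over 21 genes (percentile 100) and Dhcr7 (1.71) and Fdps (1.62) past 1.5-fold. Without cluster 2 the median was 0.17. Lysosomal genes had a median of 0.13 (percentile 99.9) with 28 of 29 within 1.5-fold, and the membrane protein gene Cd63 was at 191 and 461 CPM (2.41, 2.34 to 2.48). Among scavenger and pattern receptors (median 0.25, percentile 100) 6 of 27 were higher, including Mfge8 (3.17), a bridging molecule for apoptotic cells, and the RNA sensor gene Tlr7 (2.07), and Clec4n was lower (0.606).

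Metabolic lists stayed near 0. Lipid handling had a median log2 ratio of 0.03 with 30 of 33 within 1.5-fold, the 3 lower ones being Apoe, Apoc1 (0.580) and Scd2 (0.621). Nuclear oxidative phosphorylation genes had a median of -0.04 with all of 76 within 1.5-fold, the 13 mitochondrially encoded genes 0.01, glycolysis 0.13 with Slc2a1 higher (1.57) and Eno1 lower (0.456), stress defence and iron -0.03 with Slc11a1 higher (2.14) and Tfrc lower (0.580), and MYC targets -0.04 with Dkc1 higher (1.90). Eno1 has near-identical copies, which makes its value uncertain. Alternative activation had a median of 0.05 over 10 genes, with Ccl17 (0.316) and Irf4 (0.394) lower and Il10 (1.71) and Clec10a (1.74) higher. Ccl17 was abundant in cluster 13, and over all kept cells its ratio was 2.32.

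**Figure D4:**
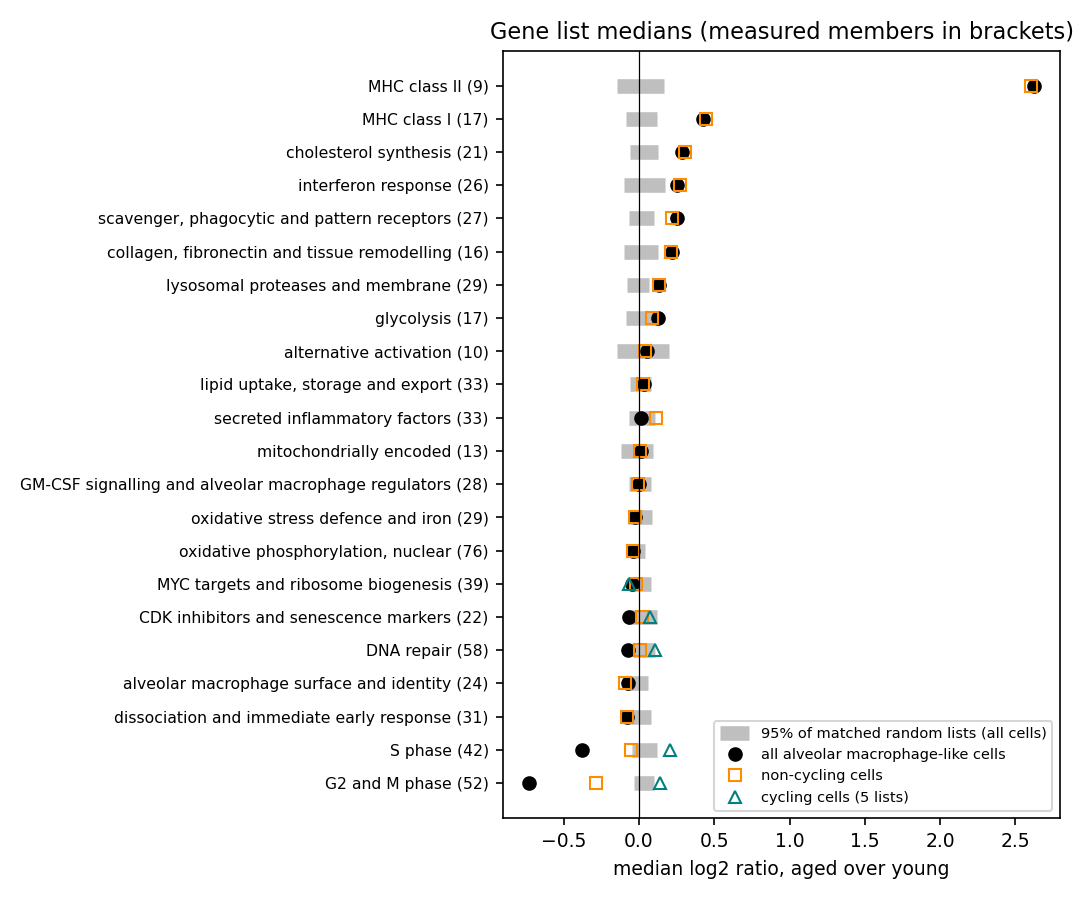
Median log2 ratio, aged over young (horizontal axis), of each gene list in all alveolar macrophage-like cells (black), non-cycling cells (orange squares) and, for 5 lists, cycling cells (green triangles), with grey bars for the middle 95% of matched random lists. MHC class II lay at 2.63 and G2 and M phase at -0.73 in all cells and at 0.14 in cycling cells.

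Markers of other cell types within alveolar macrophage-like cells were as follows. Neutrophil markers summed to 91.1 CPM in the young and 246 CPM in the aged library, led by Mmp8, S100a8 (19.5 and 57.6 CPM) and Cxcr2 (8.18 and 27.3 CPM), whereas Csf3r was at 11.95 and 10.2 CPM and Ly6g had 0 UMIs. Monocyte markers summed to 54.6 and 98.4 CPM, interstitial macrophage markers to 77.5 and 38.8 CPM, led by Apoe, and dendritic cell markers to 487 and 417 CPM. B cell markers had 14 and 15 UMIs and plasma cell markers 29 and 22 UMIs in all. Aged over young ratios were 1.02 for eosinophil, 0.923 for basophil or mast cell, 1.15 for T cell and 1.01 for NK cell markers. They were 0.948 for alveolar type 2, 1.22 for alveolar type 1, 1.02 for airway epithelial, 1.32 for endothelial and 1.22 for fibroblast markers. Single genes supplied most young UMIs of several sums. Ear6 had 624 of 624 eosinophil, Il6ra 4915 of 4927 basophil or mast cell and Txk 161 of 165 NK cell marker UMIs. Tppp3 had 10235 of 10507 airway epithelial, Calcrl 1741 of 1794 endothelial and Lat 122 of 145 T cell marker UMIs. These ratios thus describe those genes rather than the content of these cell types. Fibroblast markers had 18 and 11 UMIs in all (interval 0.522 to 2.735). Erythroid markers had 2 UMIs and 1 UMI.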

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

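Except for the test of interferon gamma-induced genes, all tests here were chosen only after the result, or part of it, was seen. TMM factors and depth per cell had been fixed beforehand as alternatives, but their use as tests of these explanations was set afterwards.

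Barcodes left out by the cell filter, in no comparison, are given because their share differed between the libraries. They made up 3.55% of the aged library (224 of 6313, 3.11 to 4.03%) against 1.19% of the young library (163 of 13753, 1.01 to 1.38%). Mitochondrial UMIs of 10% or more accounted for 163 of those left out in the young and 222 in the aged library. Alveolar macrophage markers took 2.26% of the UMIs of the aged barcodes left out and 2.47% of those of the aged cells kept, against 2.38% and 2.24% in the young library.

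MHC class II transcripts were higher in the aged library's alveolar macrophage-like cells. To bring them in, cells like those of cluster 13 would have to give 8.99% of aged UMIs, yet over 9 of that cluster's markers the median excess was 0.00395 of what this share predicts, with Cd209a at -0.00106, Ccr2 at 0.132 and Itgam the highest at 0.278, while monocyte markers summed to 1.80 times the young level. Cluster 13's profile was pooled here over both libraries, whose cells in it differed in fibroblast markers. Doublets, or a minority of cells without free RNA, are also argued against, since 87.4% of thinned aged cells held a class II UMI, and so is scaling, since the list median was 2.58 with TMM factors. Free RNA in equal amounts per droplet is argued against as the whole source, since it would leave 0.133% of thinned aged cells without a class II UMI where 12.6% (11.7 to 13.6%) had none, but up to 2.29 of the 9.26 UMIs by which the mean per cell rose stay open to it, with no class lacking class II to set its level. Presenting cells unlike cluster 13 and age stay open, untested, and a wider response of the kind interferon gamma induces was not settled. Of 13 other genes induced by it, 8 had enough UMIs, with a median log2 ratio of 0.22 at percentile 90.9, between the bounds written before it was seen. Among these, 3 were at least 1.5-fold higher, including Gbp5 (1.90) and Irgm1 (1.59), 1 was lower, Socs1 (0.595), and 4 lay between. Of those left out, Ido1, Nos2 and Tgtp2 had 0 UMIs in both libraries.

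Cell cycle transcripts were lower in the aged library. A lower depth per aged cell is argued against, since the median was 3418 UMIs in aged and 3014 in young alveolar macrophage-like cells (ratio 1.13). A lower share of cycling cells and a lower level per cycling cell cannot be told apart, because the cycling clusters were picked by high levels of the same genes. Within them the median log2 ratio of the G2 and M phase list was 0.14, and with the aged cycling and non-cycling sums mixed at the young library's proportions (15.1% of UMIs from cycling cells in place of 6.96%), it was 0.11, values that the choice of clusters largely fixes. Age stays open and untested.

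Ide, the insulin degrading enzyme gene, was at 73.8 CPM in the young and 42.1 CPM in the aged library (ratio 0.570, 0.529 to 0.613), and its neighbour Fgfbp3 had 55 and 14 UMIs (ratio 0.510, 0.262 to 0.929). Both genes were singled out after their values were seen. For Ide, a different mix of these clusters is argued against, since the median ratio within 10 clusters was 0.587, with the interval below 1 in 7 of them and a highest value of 0.854. Counts were small on one side, with 35 young UMIs in cluster 0 and 11 aged UMIs in cluster 5. The clusters were largely split by library, so different cell states within them stay open, and Fgfbp3 was not tested in this way. An effect over many neighbouring genes was not settled: the nearest 5 measured genes on each side had a median ratio of 0.880. The lowest were Kif11 (0.514), a mitosis gene, and Cep55 (0.644), both among the leading genes of cycling clusters. A DNA difference between the young and aged mice at Ide and Fgfbp3 cannot be tested with these counts and stays open, as does age, untested.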

How the results depend on the processing

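Clustering each library alone, leaving out cluster 2 and leaving out high doublet scores were tests chosen only after the data were seen. Leaving out Scrublet's doublets was not run, since it marked 1 cell. Of the recomputed values of the compared results 645 stayed the same, 33 moved past their interval (counts of genes, past 1.5 times) and 1 reversed, and of those of named genes and thinned shares 1206, 185 and 2. Named genes alone gave 1206, 169 and 2, so every recomputed thinned share moved when the thinning depth was changed or thinning left out. Except where stated, the cause was not tested. List values below are medians of log2 ratios in alveolar macrophage-like cells. With at least 1000 genes and under 5% mitochondrial UMIs, a choice that itself keeps deeper cells, the median UMIs per cell, young, were 3340 and the median UMIs per cell, aged, 3592, the median genes per cell, young, 1547 and the median genes per cell, aged, 1671, the young cycling share 13.4% and the G2 and M phase UMIs per S phase UMI 2.85 and 2.70. That ratio was 2.71 in the young library without the top 8% of doublet scores. Each library clustered alone gave cycling shares of 6.48% and 3.21%. With all barcodes the mitochondrially encoded list was at 0.12 (0.11 in non-cycling cells). Without cluster 2, mostly young and non-cycling, the young cycling share was 14.2%, the G2 and M phase list -1.01, cholesterol synthesis 0.17 (0.13 in non-cycling cells) and 50 genes were at least 2-fold lower. TMM moved log2 ratios by -0.04 and median of ratios by -0.04. The median log2 ratio, oxidative phosphorylation, nuclear list, alveolar macrophage-like cells, was -0.0789 with TMM, -0.0731 with median of ratios and -0.0720 without cluster 2. The median log2 ratio, oxidative phosphorylation, nuclear list, non-cycling alveolar macrophage-like cells, was -0.0927, -0.0931 and -0.0745. With TMM and median of ratios the median log2 ratio, MYC targets and ribosome biogenesis list, alveolar macrophage-like cells, was -0.0873 and -0.0814 (-0.0689 and -0.0693 in non-cycling, -0.13 and -0.13 in cycling cells). The median log2 ratio, G2 and M phase list, cycling alveolar macrophage-like cells, was 0.0746 and 0.0741. In non-cycling cells, by construction, S phase was at -0.0546 and G2 and M phase at -0.29, and DNA repair reversed to 0.00928. Ratios reversed for Ccl17 over all kept cells (2.32) and Cdkn2d in non-cycling cells (1.05). Few UMIs limit the genes near 1 CPM.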

Other observations

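The genes in this part outside the rule for named genes were chosen after their values were seen. Except for Cd274 and Irgm2, no test was run on them. Cdkn2a and the cycling clusters were related differently in the libraries. In young cells Cdkn2a stood at 10.4 CPM in cycling and 0.898 CPM in non-cycling alveolar macrophage-like cells, and in aged cells at 35.9 and 17.4 CPM. Lmnb1, a nuclear lamina gene, was at 32.2 CPM in the young and 20.6 CPM in the aged library (ratio 0.641), but its ratio was 0.958 (0.817 to 1.12) among cycling and 0.912 (0.780 to 1.06) among non-cycling cells.

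S100a9, which encodes the usual partner of S100a8, had 0 UMIs in young alveolar macrophage-like cells, which allows up to 0.0693 CPM, and 25 UMIs (1.16 CPM) in aged ones. The interferon gamma target Cd274, which encodes PD-L1, was at 147 and 179 CPM (ratio 1.21, 1.17 to 1.26), and Irgm2 at 4.07 and 6.11 CPM (ratio 1.501, 1.19 to 1.89). Both belong to the 8 measured genes of the interferon gamma test above, so they are not separate support.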
